A study of Mus musculus with 22 samples.

How the data were processed

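Poly-A RNA from the soleus of male mice was sequenced in 22 libraries, with WT or TRa1 KO animals given T3 or vehicle. Per the labels, RNA was purified with RNeasy columns, libraries were made with the TruSeq Stranded mRNA kit and read as 51-bp pairs on a NovaSeq instrument. The processing notes name STAR 2.7.3a, featureCounts 1.6.4, edgeR 3.26.8 and the mouse build mm10. The annotation release and the strand setting are not given in the sources used here. The deposited table holds raw counts per gene, with 1 column per library and a column of gene length in base pairs that the authors supplied. All values were whole numbers, and the column sums ranged from 14542548 to 75766782. No library was left out of the comparisons.

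The table listed 55487 genes, and 55394 of them also stand in GENCODE M21. Chromosome and strand were identical for all 55394 shared genes, and start and end were identical for 87.4% of them. Coordinates are given as in the deposited table, on mm10. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 with its minimum count of 10, which left 15082 genes. These held at least 99.94% of the counts in each library.

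The 4 groups were fitted together with TMM scaling, a negative binomial model and edgeR's quasi-likelihood test. Adjusted p-values follow Benjamini and Hochberg over the 15082 genes, and a gene was called when its adjusted p was below 0.05. The contrasts were T3 against vehicle in each genotype, KO against WT under each treatment, and the difference between the T3 responses. No covariate was used, because the labels give no batch, litter or pairing, and replicate numbers pair nothing. Errors of log2 fold changes are standard errors (SE) of the fit, and errors of library-size-scaled counts (CPM) are standard deviations (SD). The median SE was 0.19 for T3 in WT, 0.19 for T3 in KO, 0.21 for KO under vehicle, 0.17 for KO under T3 and 0.27 for the difference of responses.

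The samples, groups, comparisons, gene lists and most alternatives were fixed before the data were examined. Genes were named by a rule fixed then. Of the called genes with a mean of at least 5 CPM and group medians in the same direction, the 8 largest increases and the 8 largest decreases of each comparison were taken, leaving out unnamed gene models. To these came 21 genes followed in every comparison, among them Thra, Thrb and Ucp3, and up to 4 members of each described list with the smallest adjusted p. Some genes that the rule names are not reported here. The lists were 29 pathways or protein groups and 11 sets of cell type markers, of which 39 had a tested member. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Each call was set beside the adjusted p with an estimated correlation. As an alternative fry was run, which tests whether the genes of a list move one way on balance and does not compare the list with other genes.

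Thra was also compared between groups by two-sided exact permutation tests of log2 CPM. The ratio of the KO to the WT response to T3 was the slope of the KO fold change on the WT fold change. Genes for it were chosen in a random part of the WT libraries and measured in the rest, over 20 draws. The T3 response of WT and the genotype difference under vehicle share the WT vehicle libraries. Their covariance across genes was therefore taken with the 5 WT vehicle libraries split into 2 and 3, over 20 splits.

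Alternatives were RLE, upper quartile and total count scaling, no filter and a stricter filter of 1 CPM in 4 libraries. Further ones were DESeq2 1.42.0, limma voom with and without quality weights, robust dispersion and a fit on the 2 groups compared. The last planned ones were 1 surrogate variable from sva 3.50.0 and leaving out each library in turn. Some alternatives were chosen after seeing the data. They were a fit without 5 T3 libraries that lay apart, an offset for transcript GC content and length in each library, and an instrument form of the response ratio. The permutation tests of covariances across genes were also chosen then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

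The steps were tested on simulated data built from these libraries. With a true log2 change of 1, the test recovered 73.1% of changed genes for T3 in WT, 67.2% for T3 in KO and 50.7% for KO under vehicle. It recovered 67.2% for KO under T3 and 38.8% for the difference of responses. A true response ratio of 1 gave 0.948, and a true ratio of 0.5 gave 0.477. In the instrument form they gave 0.981 and 0.497.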

Results

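RNA from the soleus, a muscle of slow and fast fibres in the lower leg, was sequenced in mice labelled WT and in mice labelled as knockout for thyroid hormone receptor alpha 1 (TRa1 KO). The labels do not say whether the knockout was confined to muscle or covered all tissues, and the meaning of a genotype difference in soleus depends on this. Mice received triiodothyronine (T3), the active thyroid hormone, or vehicle. There were 5 WT vehicle libraries with 26336539 to 45184384 counts and 6 WT T3 libraries with 14542548 to 40647589. The 4 KO vehicle libraries held 25963636 to 29977780 counts and the 7 KO T3 libraries 18166907 to 75766782. The series title places the work in muscle and thyroid thermogenesis, and the comparisons ask how T3 changed soleus transcripts and how far this depended on the receptor. The labels do not state that each library came from its own animal, so p-values measure the spread between these samples.

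The first and second principal components held 19.6% and 17.3% of the variance, and 5 T3 libraries lay apart from the rest on them. Mitochondrial transcripts took between 11.2% of counts, in WT T3 replicate 5, and 29.5%, in WT T3 replicate 1. WT T3 replicate 5 lay at 86.3 on the first principal component, with fewer counts from long transcripts and 323 CPM of haemoglobin transcripts. WT T3 replicates 1 and 3 and KO T3 replicates 2 and 3 lay between -48.0 and -41.9 on the second, with fewer counts from GC-rich transcripts. The labels name no batch that separates these libraries. In the sample numbering of the labels, however, the libraries apart on the second component lay close together, with WT T3 replicate 2 among them. Whether this reflects the order of processing is not given and was not tested.

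**Figure D1:**
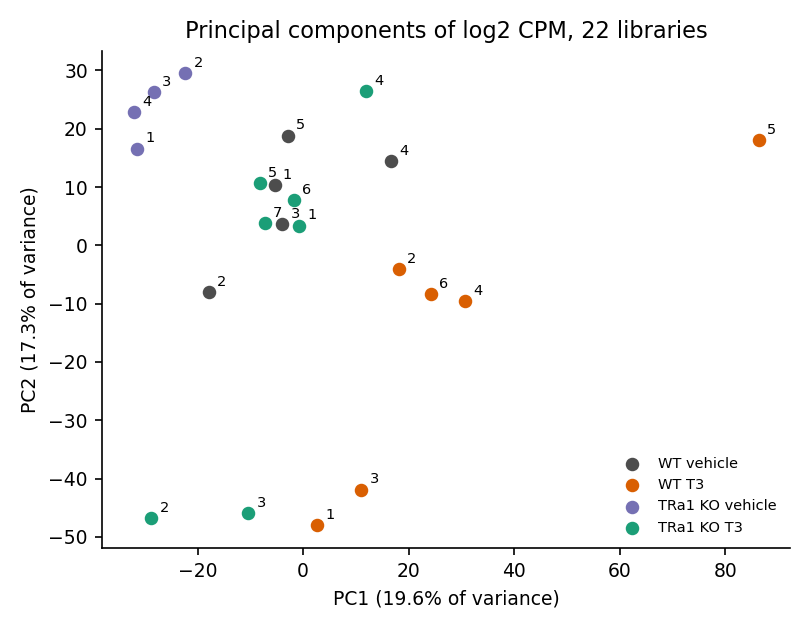
Position of the 22 libraries on the first and second principal components of log2 CPM, with 1 point per library, colours for the 4 groups and replicate numbers beside the points. WT T3 replicate 5 lies at 86.3 on the first component, and 4 T3 libraries of both genotypes lie at -41.9 or below on the second.

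Thra (ENSMUSG00000058756, chromosome 11, 98740638 to 98768403), the gene of the receptor, had 77.7 ± 8.49 CPM (SD, n = 5) in WT vehicle and 47.7 ± 4.42 CPM (n = 4) in KO vehicle. With T3 its level was 42.7 ± 13.5 CPM (n = 6) in WT and 32.6 ± 7.72 CPM (n = 7) in KO. Thra fell with T3 in WT, by 0.86 ± 0.20 on the log2 scale (adjusted p = 0.016 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The log2 fold change of KO against WT under vehicle was -0.71 ± 0.22, with an adjusted p of 0.0979 over all genes, although no KO vehicle library overlapped the WT vehicle range. For the gene alone, the two-sided exact permutation p was 0.00794, the smallest that 126 arrangements allow, and 0.0159 after adjustment over 4 such tests. The same test gave 0.00433 for T3 in WT, 0.0212 for T3 in KO (log2 fold change -0.55 ± 0.20, adjusted p = 0.188 over all genes) and 0.196 for KO under T3 (-0.39 ± 0.18, adjusted p = 0.271). WT T3 replicate 1, at 19.3 CPM, lay below every KO library (lowest 21.2), and without it Thra was called lower in KO under T3 (-0.56, adjusted p = 0.0251, over a range from 0.0106 to 0.473 in all alternatives). Counts per gene cannot separate the TRa1 and TRa2 transcripts of Thra or show a deleted exon, and 263 exonic bases are shared with Nr1d1 on the opposite strand. Thrb, the gene of the other thyroid hormone receptor, had log2 fold changes between -0.19 and 0.09 in the 4 group comparisons, none of them called.

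**Figure D2:**
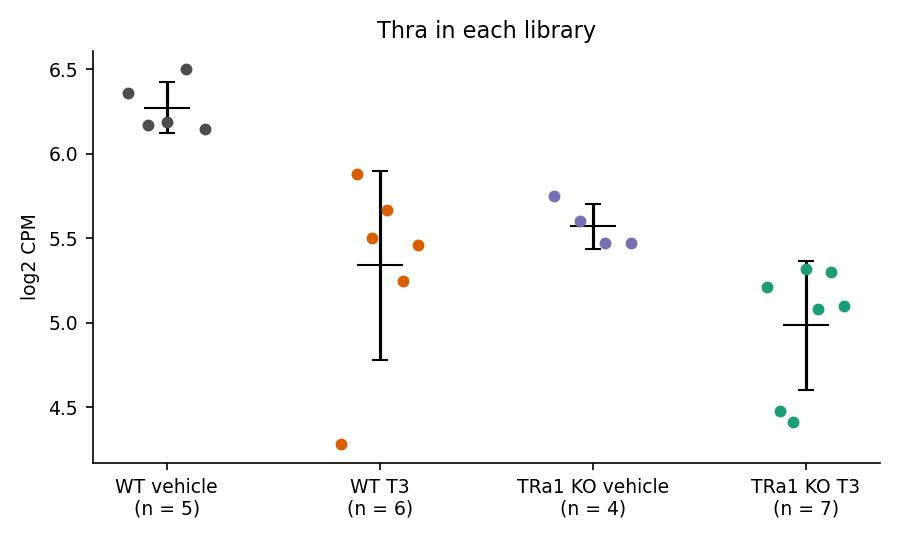
Level of Thra in log2 CPM on the vertical axis for each library, by group, with 1 point per library and bars for the mean and SD. The WT vehicle libraries averaged 6.27 ± 0.15 and the KO vehicle libraries 5.57 ± 0.13, without overlap.

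T3 in WT soleus lowered Sln and Pln, which encode inhibitors of the sarcoplasmic reticulum calcium pump, and raised Hr. Sln (sarcolipin) fell from 38.9 ± 11.6 to 5.96 ± 3.54 CPM, and Pln (phospholamban) fell by 2.85 ± 0.45 on the log2 scale. Hr, a corepressor of nuclear receptors and a known T3 target, rose from 23.5 ± 20.4 to 129.6 ± 41.5 CPM. Mettl21c, a muscle protein methyltransferase, fell from 80.8 ± 30.9 to 3.86 ± 2.66 CPM, the largest decrease among the genes named by the rule (means ± SD, n = 5 vehicle and 6 T3). In all, 499 of 15082 genes were called by edgeR's quasi-likelihood test, 259 higher and 240 lower, and 185 changed at least 2-fold.

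Among the other genes with the largest increases in WT were Arc, with a log2 fold change of 2.66 ± 0.46, Syt12 at 2.78 ± 0.31 and the noncoding transcript Foxo6os at 2.40 ± 0.25. Adamts8 and Tlcd2 rose by 2.15 ± 0.39 and 2.10 ± 0.27, and the immunoglobulin heavy chain gene Ighm by 3.02 ± 0.66, with a wide spread of 70.5 ± 61.6 CPM in the T3 libraries. Decreases took in metabolic enzymes: Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, at -2.02 ± 0.13, Acss1, a mitochondrial acetyl-CoA synthetase, at -1.64 ± 0.17, and carbonic anhydrase Car3 at -1.63 ± 0.15. The quinone reductase gene Nqo1 fell by 1.55 ± 0.13 and Dkk2, a Wnt pathway inhibitor, by 1.65 ± 0.23. The adjusted p-values of these genes ran from 1.16e-09 for Idh2 to 0.0103 for Ighm.

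Fatty acid oxidation genes lay lower after T3 in WT, with a median log2 fold change of -0.32 over 19 tested members, of which 3 were called lower and 4 were when adjusted over the list alone. The camera test gave an adjusted p of 1.39e-05, and adjusted p = 0.415 with an estimated correlation. Acadm, the medium-chain acyl-CoA dehydrogenase, fell by 0.74 ± 0.11 (adjusted p = 0.000332), Hadh by 0.49 ± 0.12 and Echs1 by 0.38 ± 0.10. Slow fibre contractile genes had a median of -0.35, with 2 of 14 called lower, Pln and Casq2 (-0.76 ± 0.18), and 3 lower adjusted over the list alone. Camera gave an adjusted p of 4.94e-05 for them, and adjusted p = 0.229 with an estimated correlation. Of 18 circadian clock genes 2 were called lower, among them Cry2 (-0.79 ± 0.10), and 3 adjusted over the list alone. The camera adjusted p was 0.000645 for this list, and adjusted p = 0.229 with an estimated correlation. Of 11 textbook T3-induced genes only Hr was called over all genes, and 4 were higher adjusted over the list alone. That list had a camera adjusted p of 0.00264, and adjusted p = 0.229 with an estimated correlation. Fast fibre contractile genes had a median of 0.14 but a mean of -0.06, with camera towards higher at an adjusted p of 0.0414, and adjusted p = 0.8 with an estimated correlation. Of these 15 genes 1 was called higher, Mylpf (0.75 ± 0.20), and 2 adjusted over the list alone. The fast list lost its camera call without any of 6 libraries, WT vehicle replicates 1 (adjusted p = 0.215), 2 (0.151) and 5 (0.098) and WT T3 replicates 2 (0.0515), 4 (0.0667) and 5 (0.283).

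Other list members called for T3 in WT were Dio3, the deiodinase that inactivates thyroid hormone (3.34 ± 0.53), the ubiquitin ligase gene Trim63 (1.16 ± 0.21) and Foxo1 (0.70 ± 0.16). Of the neuromuscular junction list, Colq, which anchors acetylcholinesterase, fell by 1.2 ± 0.22, and the lipogenic gene Acaca fell by 0.75 ± 0.14. Ucp3, the uncoupling protein of skeletal muscle, was not called, with a log2 fold change of 0.96 ± 0.31 (adjusted p = 0.0989), nor was Myh1, a fast myosin heavy chain gene, at 1.30 ± 0.37 (adjusted p = 0.0513). Fibroblast and matrix markers had a median log2 fold change of 0.49, with 0 of 8 called over all genes and 3 higher adjusted over the list alone (camera adjusted p = 0.00664, and adjusted p = 0.782 with an estimated correlation), and without WT T3 replicate 5 the camera adjusted p was 0.0985. Erythroid markers had a median of 1.64, with 0 of 5 called either over all genes or adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.782 with an estimated correlation), and a camera adjusted p of 0.0985 without WT T3 replicate 5. Smooth muscle and pericyte markers had a median of -0.39, with 0 of 7 called either way (camera adjusted p = 0.0171, and adjusted p = 0.415 with an estimated correlation). Schwann cell markers had a median of -1.23, with 1 of 6 called lower and 4 adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.8 with an estimated correlation), and a camera adjusted p of 0.283 without WT vehicle replicate 3. Camera also called nuclear genes of complex I (median 0.25, adjusted p = 0.00329), complex IV (0.31, 0.0132) and the mitochondrial ribosome (0.19, 0.000361) towards higher, and branched-chain amino acid and creatine metabolism (-0.17, 0.00911) towards lower. With an estimated correlation the adjusted p was 0.8 for the first 3 lists and 0.303 for the last. Called were 0 of 36, 1 of 15 and 1 of 76 genes higher and 1 of 10 lower, and 0, 1, 0 and 2 adjusted over the list alone. Without WT T3 replicate 5 the camera adjusted p was 0.592, 0.559 and 0.657 for the first 3. Camera called 13 of the 39 lists for T3 in WT, and 0 with an estimated correlation, while fry called 6 of the 13. Of the 13 camera calls 5 stayed without the 5 T3 libraries that lay apart. Without WT vehicle replicate 1, 2, 3 or 5 the count of called genes was 305, 325, 284 or 314, while without the 5 T3 libraries that lay apart it was 446. Of 47 named genes called for T3 in WT 24 were called without each library. Hadh (adjusted p = 0.0507) and Foxo1 (0.0667) were not called without WT vehicle replicate 1, nor was Mylpf without 5 libraries (0.108 at most, without WT vehicle replicate 3), nor Casq2 without WT vehicle replicate 1 (0.0511) or 2 (0.0679), and Echs1 was not called without any of 5 libraries (0.0765 at most, without WT vehicle replicate 5) or with total counts only.

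**Figure D3:**
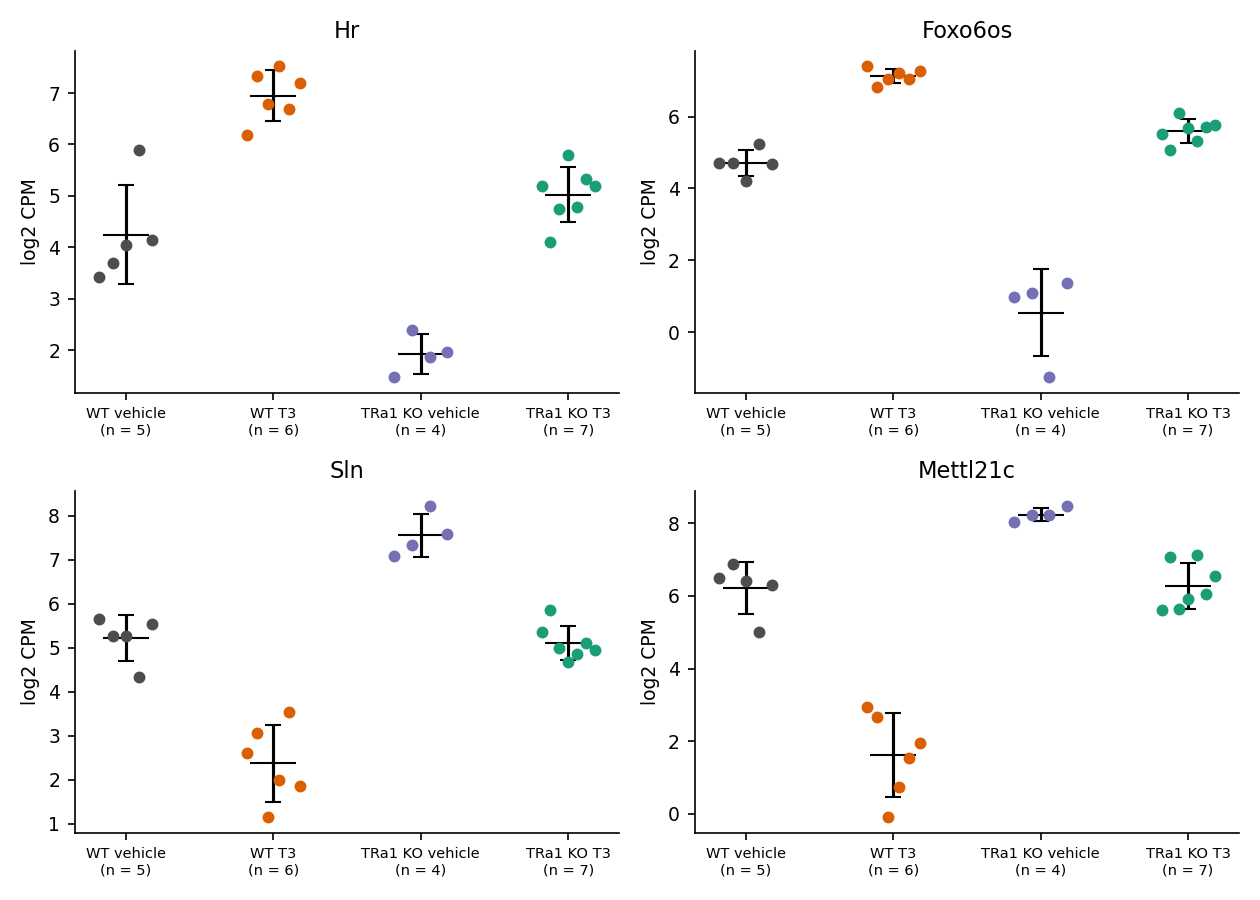
Levels of Hr, Foxo6os, Sln and Mettl21c in log2 CPM on the vertical axes for each library, by group, with 1 point per library and bars for the mean and SD. With T3 the mean of Sln went from 38.9 to 5.96 CPM in WT and from 197 to 35.9 CPM in KO.

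T3 in KO soleus changed many of the same genes in the same direction. Sln fell from 197 ± 71.5 to 35.9 ± 10.9 CPM, Pln fell by 2.67 ± 0.41 on the log2 scale and Mettl21c fell from 305 ± 37.4 to 84.5 ± 38.5 CPM. Hr rose from 3.83 ± 1.04 to 34.2 ± 12.1 CPM, and Foxo6os rose from 1.71 ± 0.94 to 49.4 ± 11.2 CPM (means ± SD, n = 4 vehicle and 7 T3). The quasi-likelihood test of edgeR called 410 genes, 254 higher and 156 lower, and 162 changed at least 2-fold.

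Further increases in KO were Syt12 (3.37 ± 0.36), Arc (2.82 ± 0.57), Ighm (2.88 ± 0.76), Sctr, the secretin receptor gene (2.39 ± 0.34), and Lpin3, a phosphatidate phosphatase gene (2.19 ± 0.14). Further decreases were G0s2, an inhibitor of triglyceride lipase (-1.70 ± 0.34), the anion exchanger gene Slc4a3 (-1.64 ± 0.30), Car3 (-1.62 ± 0.15), Car2 (-1.46 ± 0.10) and Myom2, a protein of the sarcomere M-band (-1.35 ± 0.19). Their adjusted p-values ran from 1.19e-09 for Lpin3 and Car2 to 0.0411 for Ighm.

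Of the 19 fatty acid oxidation genes 3 were called lower in KO, Acadm (-0.66 ± 0.12), Hadh (-0.48 ± 0.12) and Echs1 (-0.36 ± 0.10), and 9 adjusted over the list alone. Camera gave an adjusted p of 9.74e-09, and adjusted p = 0.288 with an estimated correlation. Of 11 textbook T3-induced genes 3 were called higher, Hr (3.16 ± 0.44), Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase (1.15 ± 0.28), and Klf9 (0.51 ± 0.13), and 3 adjusted over the list alone. The camera adjusted p of that list was 0.000517, and adjusted p = 0.259 with an estimated correlation. Dio3 rose by 3.14 ± 0.58, Idh2 fell by 1.2 ± 0.13 and Nqo1 by 0.93 ± 0.13. Of the clock genes, Cry2 fell by 0.52 ± 0.10. Smooth muscle and pericyte markers had a median of -0.52, with 0 of 7 called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.259 with an estimated correlation). Macrophage markers had a median of 0.68, with 0 of 10 called either over all genes or adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.773 with an estimated correlation). Fast fibre contractile genes had a median of 0.41, with 1 of 15 called higher and 1 adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.839 with an estimated correlation), and lost the camera call without any of 4 libraries (0.364 at most, without KO vehicle replicate 3). Fibroblast and matrix markers had a median of 0.46, with 0 of 8 called over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.839 with an estimated correlation), and lost the camera call without any of 5 (0.36 at most, without KO vehicle replicate 1). Heat shock and unfolded protein response genes had a median of 0.13, with 1 of 17 called higher and 4 adjusted over the list alone (camera adjusted p = 0.046, and adjusted p = 0.773 with an estimated correlation), and lost the camera call without any of 11 (0.147 at most, without KO T3 replicate 2). Of the 39 lists 7 were called by camera for T3 in KO, and 0 with an estimated correlation, while fry called 3 of the 7.

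Of 42 named genes called for T3 in KO 22 were called without each library. The split of the calls depended on scaling: 62.0% were higher with TMM and 76.6% with total counts only. Without KO vehicle replicate 1, 2, 3 or 4 the count was 233, 164, 245 or 200, and without WT T3 replicate 5 it was 696. That last library is not part of this comparison, but it enters the joint fit of the groups and its shared estimate of the spread. Gpd2 and Klf9 lost their call without KO vehicle replicate 3 (adjusted p = 0.123 and 0.156) and without 4 and 7 other libraries, Ighm without 9 libraries (0.139 at most, without KO vehicle replicate 4), Hadh without 5 (0.105 at most) and Echs1 without 13 (0.12 at most). Hadh and Echs1 were not called with total counts only either.

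The T3 responses of the genotypes overlapped well beyond chance, and only Foxo6os was called for a difference between them. Of the genes called in WT and KO, 122 were higher in both, against 4.4 if the calls were independent, and 93 were lower in both, against 2.5. Among the WT calls, 98.5% of the higher and 99.2% of the lower genes had the same sign in KO. Foxo6os (ENSMUSG00000084929, chromosome 4, 120291350 to 120303892, an antisense gene next to Foxo6) rose more in log2 terms in KO than in WT, by 2.44 ± 0.37 (adjusted p = 0.0164 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In CPM it went from 1.71 ± 0.94 to 49.4 ± 11.2 in KO (n = 4 and 7) and from 26.7 ± 6.76 to 141 ± 19.1 in WT (n = 5 and 6), and its level in KO T3 stayed below that in WT T3. The unadjusted p was below 0.05 for 371 of the 15082 genes, fewer than the 5% that chance alone would give. These p-values of edgeR's test thus ran higher than under chance alone, so the count is no evidence of equal responses. DESeq2 called 3 genes and limma voom 1.

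The receptor gene Thra, Sln, Hr, Ucp3, Gpd2 and the other genes followed in every comparison were not called for a difference of responses. For Sln the difference was 0.23 ± 0.45 and for Ucp3 -0.31 ± 0.44 on the log2 scale. In simulated data 38.8% of genes with a true difference of 1 on the log2 scale were called, and 4.5% of those with 0.5. The simulation drew genes independently, without trends shared by the genes of a library, so recovery in the real data may differ. Across the 15082 genes the fold changes had r = 0.58 and rho = 0.53, where genes are not independent replicates. The covariance of the responses, 0.0948, was the highest of 152460 arrangements of treatment labels within genotype (exact one-sided permutation p = 6.56e-06, the smallest possible). A GC trend shared by T3 libraries of both genotypes would add to r and to this covariance, and could raise the slope below. None of these values was taken with that trend removed. The slope of KO on WT responses in separately chosen genes was 0.881 (range 0.746 to 1.02), from the 9 of 20 draws that gave enough genes, with a median of 143 genes per draw (34 to 297). With the same genes the median ratio per gene was 0.937, and the instrument form gave 1.01. With a looser choice of genes the slope was 0.764 over 17 draws, and the instrument form gave 0.939. Noise in the measured WT change lowers the slope, which was 0.948 for a simulated ratio of 1. A slope below 1 therefore does not show a weaker response in KO. Foxo6os was no longer called for the difference without WT vehicle replicate 4 (adjusted p = 0.0584), WT T3 replicate 2 (0.0502), KO vehicle replicate 1 (0.0645) or the 5 T3 libraries that lay apart (0.0998), over a range from 4.24e-07 with DESeq2.

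**Figure D4:**
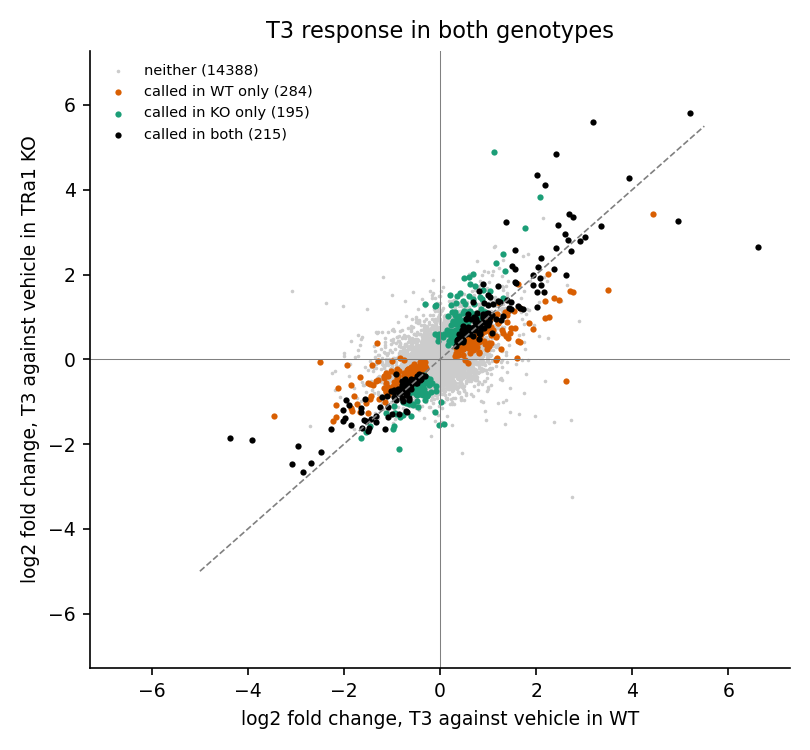
Log2 fold change of T3 against vehicle in WT on the horizontal axis and in TRa1 KO on the vertical axis, with 1 point per gene for 15082 genes and the dashed line marking equal change. The black points are the genes called in both genotypes, 122 higher and 93 lower.

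Without T3, KO soleus carried more slow fibre and less fast fibre transcript than WT soleus. Of 14 slow fibre contractile genes 8 were called higher, among them Tnni1 (1.09 ± 0.18), Tpm3 (0.77 ± 0.16) and the slow myosin heavy chain gene Myh7 (0.91 ± 0.22). Of 15 fast fibre contractile genes 9 were called lower, among them Mylpf (-1.40 ± 0.23), Tnnt3 (-1.33 ± 0.28) and the fast myosin heavy chain gene Myh2 (-1.32 ± 0.30). Fast fibre genes also mark neighbouring fast muscle that a soleus sample could hold, and this was not told apart under either treatment. The fast myosin gene Myh4 ranged from 17.8 to 8960 CPM in WT vehicle and from 9.38 to 1970 CPM in KO vehicle. The 8960 CPM came from WT vehicle replicate 4, with at most 1810 in the others of its group. That library also had the highest level of the fast fibre gene Atp2a1 in its group, 13500 CPM (6630 to 8830 in the others). Its Hr level was the highest too, at 59.7 CPM (10.7 to 17.6). Sln was higher, at 197 ± 71.5 CPM in KO (n = 4) against 38.9 ± 11.6 in WT (n = 5), and Hr lower, at 3.83 ± 1.04 against 23.5 ± 20.4 CPM. In all, 465 genes were called by edgeR's quasi-likelihood test, 236 higher and 229 lower, and 226 differed at least 2-fold.

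Adjusted over the list alone, 9 slow fibre genes were higher and 1 was lower, and 10 fast fibre genes were lower. Camera gave the slow list an adjusted p of 1.8e-08, and adjusted p = 0.0779 with an estimated correlation. It gave the fast list an adjusted p of 6.91e-14, and adjusted p = 0.0779 with an estimated correlation. Of the calcium pump genes, Atp2a2 (slow fibres) was higher at 0.62 ± 0.16 and Atp2a1 (fast fibres) lower at -0.83 ± 0.23. Of 12 glycogen metabolism genes 3 were called lower, Gys1 (-0.46 ± 0.12), Phkg1 (-1.08 ± 0.28) and Phka1 (-0.66 ± 0.18), and adjusted over the list alone 7 were lower and 1 higher. The camera adjusted p was 0.0014, and adjusted p = 0.123 with an estimated correlation. In the list of uncoupling and ion-pump genes, 2 of 17 tested were higher, Sln and Atp2a2, and 3 were lower, among them Gpd2 (-1.22 ± 0.30) and Atp2a1, and adjusted over the list alone 2 were higher and 7 lower. Its camera adjusted p was 0.0145 towards lower, and adjusted p = 0.0779 with an estimated correlation. Camera also called 6 other lists towards lower in KO vehicle. Mitochondrially encoded subunits had a median of -0.45 (adjusted p = 0.0151), nuclear genes of complex I -0.16 (0.0266), the mitochondrial ribosome -0.13 (0.0151), the tricarboxylic acid cycle -0.20 (0.0135), glycolysis and glucose uptake -0.28 (0.0277) and textbook T3-induced genes -0.20 (0.0261). In the same order, the adjusted p with an estimated correlation was 0.653, 0.88, 0.88, 0.653, 0.68 and 0.375, and 0 of 11, 0 of 36, 0 of 76, 1 of 18, 1 of 15 and 3 of 11 genes were called lower, the same counts adjusted over the list alone. Without 1 library the camera adjusted p reached 0.0361, 0.1, 0.151, 0.0745, 0.124 and 0.0597. Towards higher it called the muscle atrophy programme (median 0.16, adjusted p = 0.0425, and adjusted p = 0.653 with an estimated correlation) and neuromuscular junction genes (0.19, adjusted p = 0.0424, and adjusted p = 0.375 with an estimated correlation), with 1 and 2 of 12 genes higher. Adjusted over the list alone 3 were higher in the first and 4 higher and 2 lower in the second, and the camera calls ended without any of 6 libraries (0.11 at most) and 5 libraries (0.0904 at most). For KO under vehicle 12 of the 39 lists were called by camera, and 0 with an estimated correlation, while fry called 5 of the 12.

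Among the largest differences outside these lists, KO vehicle had higher Mettl21c (1.92 ± 0.43), the acyl-CoA thioesterase gene Acot1 (1.83 ± 0.34), Itm2a (1.83 ± 0.20), the sodium channel subunit gene Scn3b (1.80 ± 0.34) and the collagen gene Col23a1 (1.79 ± 0.16). Lower were Foxo6os (-3.96 ± 0.32), its neighbour Foxo6 (-2.64 ± 0.50), Prune2 (-2.58 ± 0.36), the potassium channel gene Kcng4 (-2.29 ± 0.50), Arc (-2.19 ± 0.59), Gnal (-1.84 ± 0.38) and Prr33 (-1.80 ± 0.25). Colq (1.32 ± 0.24) and the acetylcholine receptor gene Chrna1 (0.97 ± 0.12) were higher, as was Nqo1 (1.06 ± 0.15). The globin gene Hbb-bt was called higher at 3.55 ± 0.92, with 917 CPM of haemoglobin transcripts in KO vehicle replicate 3, and without that library its adjusted p was 0.781.

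With total counts only, 75.7% of the genes called under vehicle were higher in KO against 50.8% with TMM, and the median log2 fold change of all genes moved to 0.13. Without WT vehicle replicate 3 or 4 the count of calls was 287 or 251, without KO vehicle replicate 2, 3 or 4 it was 266, 237 or 212, and without WT T3 replicate 5 it was 788. That last library is outside this comparison and enters only the joint fit of the groups. Of 45 named genes called under vehicle 22 were called without each library. The call ended without any of 16 of the 22 libraries for Atp2a1 (adjusted p = 0.202 at most), 13 for Phka1 (0.155), 10 for Atp2a2 (0.14), 8 for Gys1 (0.19), 7 for Arc (0.159), 6 for Hbb-bt, 5 for Myh7 (0.0772), 4 for Phkg1 (0.142) and 3 each for Myh2 (0.0785) and Gpd2 (0.118). For Tnnt3 (0.0517) and Kcng4 (0.0512) it ended without KO vehicle replicate 4 alone. Atp2a1, Gys1, Phka1 and Phkg1 were not called with total counts only either.

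**Figure D5:**
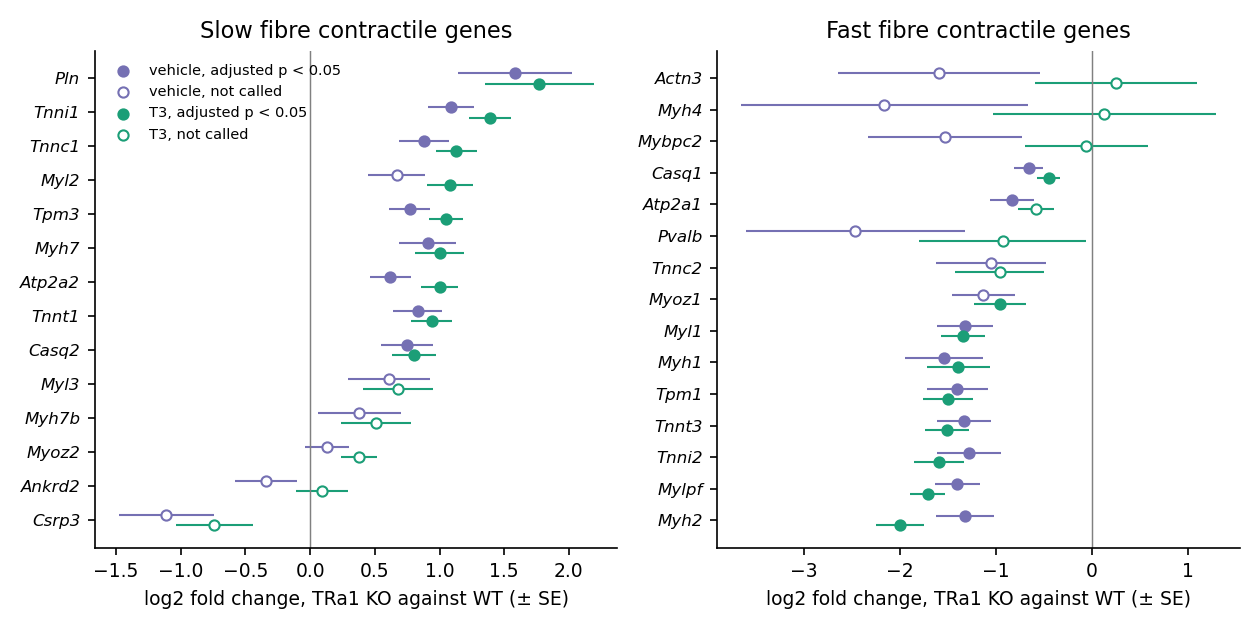
Log2 fold change of TRa1 KO against WT on the horizontal axes for the 14 slow and 15 fast fibre contractile genes, under vehicle and under T3, with bars for the SE and filled points for called genes. Under T3, 9 slow genes were called higher and 9 fast genes lower.

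Under T3 too, KO soleus carried more slow fibre and less fast fibre transcript than WT soleus. Of 14 slow fibre genes 9 were called higher in KO, with Tnni1 at 1.39 ± 0.16, Tpm3 at 1.05 ± 0.13, Atp2a2 at 1.00 ± 0.14 and Myh7 at 1.00 ± 0.19. Of 15 fast fibre genes 9 were called lower, with Mylpf at -1.71 ± 0.18, Myh2 at -2.00 ± 0.25, Tnni2 at -1.59 ± 0.26 and Myh1 at -1.39 ± 0.33. Mettl21c had 84.5 ± 38.5 CPM in KO (n = 7) against 3.86 ± 2.66 in WT (n = 6), and Sln 35.9 ± 10.9 against 5.96 ± 3.54 CPM. There were 840 called genes by edgeR's quasi-likelihood test, 487 higher and 353 lower, and 322 differed at least 2-fold.

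Adjusted over the list alone, 11 slow fibre genes were higher and 1 was lower, and 10 fast fibre genes were lower. The slow list had a camera adjusted p of 6.44e-13, and adjusted p = 0.0132 with an estimated correlation, the only list of the 39 in any comparison that passed both ways, while 17 were called by camera in this comparison, 5 of them also by fry and 6 also without the 5 T3 libraries that lay apart. The fast list had a camera adjusted p of 6.44e-13, and adjusted p = 0.129 with an estimated correlation. Nuclear genes of complex I lay lower, with a median of -0.39 over 36 genes, 2 of them called, Ndufa1 (-0.62 ± 0.15) and Ndufb5 (-0.52 ± 0.15), and 12 lower adjusted over the list alone. Camera gave an adjusted p of 1.36e-09, and adjusted p = 0.385 with an estimated correlation. Of 76 mitochondrial ribosome genes 1 was called lower, Mrpl46 (-0.48 ± 0.13), and none adjusted over the list alone (camera adjusted p = 3.84e-09, and adjusted p = 0.405 with an estimated correlation). Without the 5 T3 libraries that lay apart the camera adjusted p was 0.0153 for complex I and 0.0857 for the mitochondrial ribosome, and Ndufa1, Ndufb5 and Mrpl46 were not called, as with total counts only. Endothelial markers had 2 of 8 called lower, Emcn (-0.59 ± 0.14) and Kdr (-0.68 ± 0.18), and 2 adjusted over the list alone (camera adjusted p = 0.00181, and adjusted p = 0.307 with an estimated correlation). The other lists that camera called towards lower were complexes II and III (median -0.30, adjusted p = 0.0016), complex IV (-0.37, 0.0002), complex V (-0.29, 0.00229), mitochondrially encoded subunits (-0.49, 0.0016), the tricarboxylic acid cycle (-0.20, 0.00269), glycolysis and glucose uptake (-0.37, 0.0016), glycogen metabolism (-0.26, 0.00426), the proteasome (-0.15, 0.00269), textbook T3-induced genes (-0.25, 0.0306) and smooth muscle and pericyte markers (-0.22, 0.0239). In that order the adjusted p with an estimated correlation was 0.385, 0.405, 0.505, 0.385, 0.405, 0.405, 0.307, 0.585, 0.381 and 0.381. Adjusted over the list alone, 1 of 14, 1 of 15, 1 of 16, 0 of 11, 6 of 18, 10 of 15, 4 of 12, 0 of 31, 3 of 11 and 0 of 7 genes were lower, with 1, 1, 1, 0, 2, 1, 1, 0, 1 and 0 lower over all genes. Higher adjusted over the list alone were 2 genes of the tricarboxylic acid cycle and 1 each of glycolysis and the textbook list. Towards higher camera called the muscle atrophy programme (0.32, adjusted p = 0.0306, and adjusted p = 0.385 with an estimated correlation) and the circadian clock (0.18, adjusted p = 0.0181, and adjusted p = 0.381 with an estimated correlation), with 1 of 12 and 2 of 18 genes higher and 4 and 3 adjusted over the list alone. Without WT T3 replicate 5 the camera adjusted p was 0.0678 for complexes II and III and for complex IV, 0.173 for complex V, 0.0664 for glycolysis, 0.734 for the proteasome and 0.0682 for the clock. The camera call ended without any of 4 libraries for the textbook list (0.0697 at most), 5 for the atrophy programme (0.0943) and 2 for smooth muscle markers (0.0983).

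Also higher in KO under T3 were Pln (1.77 ± 0.42), Tecrl (2.48 ± 0.33), Scn3b (1.95 ± 0.31), the adhesion receptor gene Adgrg2 (1.73 ± 0.27), the kinase gene Cdkl1 (1.73 ± 0.23), Ndrg4 (1.73 ± 0.44), Nqo1 (1.68 ± 0.13) and Idh2 (1.26 ± 0.12). Lower were Ighm (-2.57 ± 0.56), Prune2 (-2.34 ± 0.28), Arc (-2.03 ± 0.39), Hr (-1.92 ± 0.33), Prr33 (-1.56 ± 0.20) and Foxo6os (-1.52 ± 0.22). Of 12 neuromuscular junction genes 4 were higher and 2 lower, the same counts adjusted over the list alone, among them Chrna1 (0.99 ± 0.10), Colq (1.63 ± 0.21), Chrnb1 (-0.87 ± 0.15) and Musk (-1.01 ± 0.23), with a camera adjusted p of 0.085, and adjusted p = 0.385 with an estimated correlation. The autophagy genes Gabarapl1 (0.90 ± 0.17) and Bnip3 (0.71 ± 0.14) were higher. Between treatments, 166 genes were higher and 143 lower in KO in both, against 7.6 and 5.4 if the calls were independent, and the difference between these comparisons is the test in which only Foxo6os was called.

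With total counts only, 1459 genes were called under T3 and 85.9% of them were higher in KO, against 58.0% with TMM, and the median log2 fold change of all genes moved to 0.16. No left-out library moved the count of 840 by more than 1.5 times, and of 56 named genes 45 were called without each library. The call ended without any of 11 libraries for Ndufb5 (adjusted p = 0.1 at most), 4 for Kdr (0.0724), 3 for Ndrg4 (0.0523) and without KO T3 replicate 5 alone for Mrpl46 (0.0538). Without the 5 T3 libraries that lay apart, Pln, Bnip3, Myh1, Emcn and Kdr were not called, and with total counts only Emcn and Kdr were not.

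The genotype difference without T3 ran against the T3 response of WT. Of the 259 genes that T3 raised in WT, 39 were called lower in KO vehicle and 4 higher. Of the 240 that T3 lowered, 43 were called higher in KO vehicle and 3 lower. Sln, Mettl21c, Nqo1 and Colq fell with T3 and were higher in KO vehicle, and Hr, Foxo6os and Arc rose with T3 and were lower. With the WT vehicle libraries split so that the comparisons shared none, the fold changes had a median r of -0.203 across genes (range -0.314 to -0.111), and the covariance was below 0 in 20 of 20 splits. With shared libraries r was -0.082, whereas simulated data without any effect gave 0.486 when libraries were shared and -0.00292 when split.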

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

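The tests of RNA from other cell types in WT T3 replicate 5, of transcript levels of its markers, of genes within 1 Mb of Thra and of permuted labels were chosen after the results were seen, and so was the rule for reading counts near Thra. Of 156 groups of 4 to 7 libraries examined for a library far from the others, 22 had one, against 7.8 by chance. Their values are given here with the range of the other libraries of the group.

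WT vehicle replicate 4 had 45184384 counts (26336539 to 31655101), and on the log2 CPM scale Hr was at 5.9 (3.43 to 4.14), Gpd2 at 5.67 (3.74 to 4.29) and Sln at 4.34 (5.28 to 5.65). KO vehicle replicate 1 had 29977780 counts (25963636 to 26542725), 22.7% of them mitochondrial (15.6 to 16.3) and 27.3% from the 10 most abundant genes (21.3 to 22.3), with Nr1d1 at 6.85 log2 CPM (5.92 to 5.99). KO vehicle replicate 3 had Thrb at 4.33 (5.21 to 5.29), Me1 at 6.84 (7.07 to 7.1), Ucp2 at 6.33 (4.47 to 4.77) and Foxo6os at -1.26 log2 CPM (0.97 to 1.36). Its median Spearman correlation with the other libraries was 0.9779 (0.982 to 0.9823) and its endothelial markers deviated by 0.15 (-0.19 to -0.14), a mean log2 deviation from all libraries. WT T3 replicate 1 had Myh4 at 6.03 log2 CPM (8.77 to 10.22) and endothelial markers at -0.16 (0.14 to 0.3). KO T3 replicate 4 had endothelial markers at 0.29 (-0.44 to -0.17) and tendon markers at -1.42 (0.1 to 1.11). WT T3 replicate 5 had a median Spearman correlation of 0.9512 (0.9769 to 0.9826), Thrb at 4.6 (5.26 to 5.57), Atp2a2 at 12.04 log2 CPM (12.64 to 12.95) and adipocyte markers at 1.8 (-0.56 to 0.05).

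WT T3 replicate 5 stood apart from the other 21 libraries, and no biological explanation was tested, because the labels give it none. The transcript GC and length trend was not the whole cause, since with the trend removed its median Spearman correlation rose to 0.967 and still ranked 1 from the lowest of the 22, below the next at 0.9765. RNA from other cell types may have contributed: after the trend was removed, markers of 5 of the 8 non-muscle cell types lay above every other WT T3 library, among them adipocyte (1.38 against at most 0.03) and fibroblast markers (1.02 against at most 0.67). Before that removal, abundant markers were higher for the adipocyte, with Fabp4 at 584 CPM (272 to 347 in the other WT T3 libraries) and Cfd at 87.7 (3.12 to 23), and for the macrophage, with Lyz2 at 70.4 (16.4 to 33.2), but lower for the endothelium, with Pecam1 at 87.2 (106 to 147) and Flt1 at 76.1 (111 to 145), and for the pericyte, with Rgs5 at 409 (515 to 603) beside Acta2 at 52.7 (23.2 to 56.1). With the trend removed, endothelial markers lay at 0.19 (-0.07 to 0.26) and smooth muscle markers at -0.12 (-0.27 to 0.22). Both were within the range of the other WT T3 libraries, so markers did not rise for every cell type. Whether a lower share of muscle RNA would raise all other cell types alike was not tested. Such a lower share and more RNA of certain cell types therefore both stay open.

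Genes called for genotype under both treatments and not for T3 were examined near Thra, where a genome segment linked to the knockout allele would leave differences that are not effects of the receptor. Within 20 Mb lay 6 of 203 such genes, 2.96% against 3.38% of all tested genes (one-sided Fisher's exact p = 0.688). Within 1 Mb 2 of 37 tested genes were such calls, Wipf2 and Krt222, a higher share than the 203 of 15081 genes over the genome. Krt222, 0.492 Mb from Thra and singled out after its values were seen, had log2 fold changes of 1.48 ± 0.19 under vehicle and 1.01 ± 0.16 under T3. For comparison, clustering of muscle-expressed genes would place T3 calls there too, and 2 of 113 lay within 20 Mb (one-sided Fisher's exact p = 0.899). The bounds set beforehand counted such p-values against both explanations, but they were wrong, since the odds ratios of 0.869 (95% interval 0.313 to 1.94) and 0.513 (0.0612 to 1.91) allow an excess and a 20 Mb window dilutes a shorter segment, so neither is excluded.

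The genotype difference under vehicle ran against the T3 response of WT, and a biological hypothesis is that KO soleus without T3 lay on the low side of the T3 response. Shared WT vehicle libraries could not be the cause, because sharing adds a positive covariance by construction. The highest of 20 covariances with those libraries split was -0.019, an outcome that this fixed in advance as far as sharing goes. The GC and length trend was not the cause, with a highest covariance of -0.0224 once it was removed. With group labels permuted over the 15 libraries, which tests for any effect of treatment or genotype, the exact one-sided permutation p was 0.0093 over all genes and 0.00428 with the trend removed. A fibre type shift may account for it and cannot be told apart from an effect on T3 targets: over the 11124 genes that did not follow the fibre score the median covariance was -0.0243 and the permutation p 0.0804, against 0.00138 over the 3958 that did. The bound set beforehand, the lowest simulated covariance of -0.00277, was passed but was wrong, because the simulation drew genes independently and so gave too narrow a range.

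The T3 response of Foxo6os differed between genotypes by 2.44 ± 0.37 on the log2 scale, the only such gene by edgeR, with 3 genes by DESeq2 and 1 by limma voom. The unadjusted p was below 0.05 for 371 genes, fewer than the 5% that chance alone would give, which does not show that the responses were equal. Its call ended without WT vehicle replicate 4 (adjusted p = 0.0584), WT T3 replicate 2 (0.0502) or KO vehicle replicate 1 (0.0645), over a range from 4.24e-07 to 0.0998. Of the 39 lists 10 also differed in response by camera, none of them with an estimated correlation or with fry. Adjusted p-values were 0.000146 for complex I, 0.0268 for complexes II and III, 0.0052 for complex IV, 0.00666 for complex V, 0.0013 for the mitochondrial ribosome, 0.00616 for the proteasome and 0.000456 for erythroid markers, all with a lower log2 response in KO. They were 0.000146 for the circadian clock, 0.0148 for slow fibre genes and 0.0397 for regulators of mitochondrial biogenesis, whose median log2 fold changes with T3 were -0.34 in WT and -0.03 in KO, -0.35 and -0.08, and -0.12 and 0.03, where the regulators were not called for T3 in WT and none of the 3 for T3 in KO. With an estimated correlation the adjusted p was 0.2 for the clock, 0.656 for the regulators and for erythroid markers and 0.725 for the other 7. Adjusted over the list alone, 5 of 5 erythroid genes were called and 0 genes of the other 9 lists. Without WT T3 replicate 5 the camera adjusted p was 0.64 for complex I, 0.54 for complexes II and III, 0.718 for complex IV, 0.64 for complex V, 0.64 for the mitochondrial ribosome, 0.939 for the proteasome and 0.264 for the regulators. It was 0.165 for erythroid markers without KO vehicle replicate 3 and at most 0.109 for slow fibre genes, without WT T3 replicate 3. Without the 5 T3 libraries that lay apart only the clock passed, at an adjusted p of 0.0114.

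With the library labels exchanged between groups, chance was excluded for 4 of the counts of called genes. For the count of 1 for the difference of responses it was not excluded. The real split was the only 1 of 100 with as many calls for T3 in WT, with 499 against at most 20 in another split. The same held for T3 in KO with 410 against at most 1, for KO under vehicle with 465 against at most 3 and for KO under T3 with 840 against at most 113. For the difference of responses, with 1 real call, 4 of 100 splits had as many, a share under 0.05, and the highest other had 223. That split gave 4 of the 5 WT vehicle libraries the KO label and all 4 KO vehicle libraries the WT label. It thus followed a structure of the samples, the genotype. These splits exchanged genotype labels within each treatment, so they moved the genotype difference as well. The bound set beforehand, a share of 0.05, was passed, but such splits cannot decide whether a count of 1 arose by chance.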

How the results depend on the processing

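The fits without the 5 T3 libraries that lay apart and with a GC and length offset, and the instrument form of the response ratio, were chosen after seeing the data. Every other alternative was fixed beforehand, and each of those was run. Over all alternatives, 258 of 321 main values kept their direction and side of the threshold, or stayed within 1.5 times for a count. For the response ratio and the correlation of T3 response and genotype difference, the bound was the SD over draws or splits. Of 9217 values of named genes 8481 kept direction and side of the threshold, 690 lost a call, 46 gained one and 0 reversed. Of 5460 list results 5124 kept both, 250 lost a call, 82 gained one and 4 reversed. Of the list calls by camera, 58 ended with an estimated correlation and 40 with fry, which gained 2. Genes and lists that were uncalled both ways count as kept whatever their sign. The cause of the changes given here was not tested unless stated.

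Counts of called genes moved as follows, in the order T3 in WT, T3 in KO, KO under vehicle and KO under T3 where all are given. The GC and length offset gave 771, 749, 713 and 1315, 1 surrogate variable 1054, 739, 841 and 1275, and voom with quality weights 767, 1472, 1971 and 1478. DESeq2 gave 832 for T3 in WT, 660 for T3 in KO and 728 for KO under vehicle. A fit on the 2 groups compared, with fewer samples to estimate the spread, gave 291 for T3 in WT, 709 for KO under vehicle and 539 for KO under T3. Without the 5 T3 libraries that lay apart 682 genes were called for T3 in KO and 1032 for KO under vehicle, and 89.5% and 100% of the genes called with all libraries were among them. For T3 in WT and KO under T3 that share was 62.7% and 54.3%. Total counts only gave 1459 for KO under T3. For the difference of responses DESeq2 gave 3 genes, no filter, quality weights and the GC and length offset gave 2 each, and the fit without the 5 libraries gave 0 by edgeR.

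Leaving out each library in turn gave 284 (without WT vehicle replicate 3) to 563 (without WT T3 replicate 2 or 5) for T3 in WT, and 164 (without KO vehicle replicate 2) to 696 (without WT T3 replicate 5) for T3 in KO. It gave 212 (without KO vehicle replicate 4) to 788 (without WT T3 replicate 5) for KO under vehicle, 663 (without WT T3 replicate 4) to 1150 (without WT T3 replicate 5) for KO under T3 and 0 to 2 for the difference of responses.

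Thra under T3 in WT was at -0.87 with an adjusted p of 0.0516 in the fit on 2 groups, and between -0.97 and -0.71 without each library (adjusted p 0.00814 to 0.039). The fall was smaller without the 5 T3 libraries that lay apart, at -0.59 (0.00383), and with the GC and length offset, at -0.73 (0.0015). For T3 in KO it was -0.40 (adjusted p = 0.0214) without the 5 T3 libraries and -0.49 (0.0368) with the GC and length offset, and -0.61 to -0.47 without each library, called only without WT T3 replicate 1 (0.0483). For KO under vehicle it was -0.71 (0.00508) with quality weights, -0.69 (0.00238) on 2 groups, -0.73 (0.0239) with a surrogate variable, -0.68 (0.00032) without the 5 libraries and -0.59 (0.0198) with the offset. Without each library it was -0.77 to -0.64, called only without WT T3 replicate 1 (0.0279). That library is part of neither this comparison nor T3 in KO, but it enters the joint fit of the groups. For KO under T3 it was -0.49 (0.0106) without the 5 libraries and -0.56 (without WT T3 replicate 1, 0.0251) to -0.28 without each library.

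The response ratio was 0.764 with genes chosen at a threshold of 0.2, and 0.764 with genes chosen and measured on all WT libraries. In the instrument form it was 1.01, and 0.939 with genes chosen at 0.2. The correlation of T3 response and genotype difference was -0.282 over genes of at least 5 CPM and -0.082 with WT vehicle libraries shared, which adds a positive covariance by construction. For the difference of responses, 3 list results reversed without the 5 libraries, complex IV (adjusted p = 0.843), complex V (0.898) and the mitochondrial ribosome (0.564), and the last also without WT T3 replicate 5 (0.64), the highest value without 1 library, with 1.42e-06 the lowest (without WT vehicle replicate 1). Simulated changes of 0.5 on the log2 scale were recovered for 14.9% of genes for T3 in WT, 19.4% for T3 in KO, 10.4% for KO under vehicle, 22.4% for KO under T3 and 4.5% for the difference of responses, so changes of that size were mostly not detectable with these libraries.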

Other observations

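Some transcripts induced by interferon, a group not among the lists fixed beforehand, were higher after T3. The group was noticed in the data, and the list of 31 tested genes and its test were chosen after the result was seen. In WT 14 of them were called higher, among them Ifi44 (2.02 ± 0.32), Ifit1 (1.43 ± 0.30) and the antiviral enzyme gene Oas2 (1.32 ± 0.25), and in KO 5 were, among them Ifi44 (1.6 ± 0.34), Ifit1 (1.21 ± 0.31) and Oas2 (1.03 ± 0.26). For this set, camera p-values were adjusted over the comparisons rather than over the lists of a comparison. They thus cannot be set beside those of the lists fixed beforehand. The camera adjusted p was 1.19e-21 in WT, and adjusted p = 0.0318 with an estimated correlation (unadjusted p = 0.00636). Whether the set in WT would pass when adjusted over the lists of a comparison was not tested. In KO the camera adjusted p was 5.5e-12, and adjusted p = 0.0971 with an estimated correlation. A rise of the set with T3 therefore stays open in both genotypes. The difference of responses had a camera adjusted p of 9.85e-06, and adjusted p = 0.28 with an estimated correlation. These p-values are optimistic, because the same data raised the question.

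Several genes tied to thyroid hormone or muscle heat production were called in none of the comparisons. Over the 4 group comparisons the log2 fold change of Ppargc1a, a regulator of mitochondrial biogenesis, lay between -0.25 and -0.14, and that of Dio2, the deiodinase that activates thyroid hormone, between -0.33 and 0.24. For Pdk4, an inhibitor of pyruvate dehydrogenase, it lay between -0.01 and 0.57. Ucp1, the uncoupling protein of brown fat, had 26 counts in 8 of the 22 libraries and was not tested. None of the 7 lymphocyte marker genes had enough counts to be tested.

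Haemoglobin transcripts ranged within groups from 42.7 to 67.8 CPM in WT vehicle, from 72.0 to 323 CPM in WT T3, from 22.0 to 285 CPM in KO T3 and from 31.9 to 917 CPM in KO vehicle, the highest in KO vehicle replicate 3. The GC content and length of transcripts accounted for 23.6% to 39.9% of the variance within WT T3 replicates 1 and 3 and KO T3 replicates 2 and 3. It accounted for as much in KO T3 replicate 4 (38.1%), where the GC trend ran the other way with a slope of 0.0292, and in WT T3 replicate 5 (36.9%). Whether that trend, the order of the samples or a stronger T3 response set the first 4 apart was not tested.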
